A study of Mus musculus with 11 samples.

How the data were processed

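NIH-3T3 cells, an established line of mouse embryonic fibroblasts, had been treated with 10 µM AS1411 or with 10 µM of a control DNA oligonucleotide for 24 h or 48 h, and polyadenylated RNA was sequenced. The 11 libraries were placed in groups by their titles: 3 AS1411 and 3 control libraries at 24 h, and 2 AS1411 and 3 control libraries at 48 h. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be in part technical.

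The authors deposited a table of raw counts per gene and a table of normalized values for the same 15022 genes and 11 libraries. Per the submitters' processing notes, reads were handled with bcl2fastq, cutadapt, STAR, HTSeq and DESeq2 on the mouse build GRCm38, and the versions and settings of these tools are not given in the sources used here. Strandedness and the treatment of reads that map to several places are likewise not given in the sources used here. In the deposited signal table, each value was the raw count divided by a size factor of its library: multiplying back returned every value within 0.01 reads, with a largest difference of 0.0064 reads. These factors equalled DESeq2's median-of-ratios factors with a largest relative difference of 3.98e-08. No gene had a total below 8 counts over the libraries, so genes with lower totals were not analysed here. Gene identifiers were matched to GENCODE release M21 on GRCm38, where 14973 were found and 49 were not.

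Total counts per library ran from 13541951 to 18784497. All main tests used the deposited counts. Genes were filtered with edgeR's filterByExpr by group, which left 13040 genes, and library sizes were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted over all 11 libraries (edgeR 4.0.16, R 4.3.3, robust settings, 7 residual degrees of freedom). The comparisons were AS1411 against control oligo at 24 h and at 48 h, the difference between those effects (the interaction), and 48 h against 24 h in control cells. The time change within AS1411 cells was computed as context. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Expression levels are CPM, counts scaled to a common TMM-adjusted library size, given as mean ± SD.

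Before the data were examined, 31 gene lists with 883 entries were fixed, 5 of them markers of other cell types. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and again with a correlation estimated per list and with fry. Adjustment was over lists. The samples, the comparisons, the main model, the rule for named genes and most alternatives were also fixed before the data were examined.

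The rule for named genes took, at each time, the 10 higher and 10 lower genes with the largest absolute log2 fold change among those past the threshold, with an average log2 CPM of at least 2 and no overlap between AS1411 and control libraries, leaving out predicted or clone-named genes. It added up to 4 members with the smallest adjusted p of each list described, and always Ncl, Npm1, Mtor, Kpnb1 and Kif5b. For the interaction and for time in control cells it took the 5 genes with the smallest adjusted p in each direction. The rule did not say which lists count as described. After the values had been seen, and to limit length, members were named only for lists that camera called, and the remaining lists are given as counts. Members of the marker lists and of the lists added later fall outside the rule where they are named. A few genes that the rule selected are not reported here and were not replaced.

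The model was tested on simulated counts drawn from the real means, library sizes and dispersions of the 13040 genes, with 200 genes changed in each of 10 simulations per comparison. A further 30 genes were raised 1.25-fold as a list and are not in the recovered shares below. For the 24 h comparison, 57.6% of genes changed 1.25-fold, 80% of those changed 1.5-fold, 92.2% of those changed 2-fold and 97.8% of those changed 3-fold were recovered. For the 48 h comparison the shares were 50.2%, 77.6%, 90.2% and 96.4% for the same folds. False calls made up 5.96% of calls at 24 h (2.84% to 9.23% over simulations) and 5.17% at 48 h (3.31% to 7.82%), against a nominal 5%. The number of simulations was raised to 10 after a single one had been seen for each comparison, and those are among the 10. Simulated genes were independent of each other, so this test says nothing about lists of genes that vary together. Each gene also had the same dispersion in every simulated library. The real libraries of a group differed more at 48 h than at 24 h. The shares of false calls do not cover such unequal spread. Far more genes were called in the data (3878 at 24 h and 7548 at 48 h) than were changed here. The adjusted threshold depends on the share of genes changed, so recovery in the data may differ.

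Alternatives fixed beforehand were RLE, upper-quartile and library-size-only scaling, no count filter or a filter of CPM above 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited normalized value plus 1, a fit of only the groups compared, the replicate number as a block, a non-robust fit, a threshold of 0.01, and leaving out each library in turn. A fit with per-library offsets for GC content and exon length (loess span 0.3) was added after seeing the data. No spike-in was used in the sources given here, so all changes are relative to the other transcripts. Genes that share sequence with near-identical copies, among them ribosomal protein genes, mitochondrially encoded genes and Prl2c2, are uncertain to the extent that the authors' counting dropped or split their reads.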

Results

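AS1411 is a 26-nt DNA aptamer (GGTGGTGGTGGTTGTGGTGGTGGTGG) rich in guanine that forms G-quadruplexes and binds nucleolin, an abundant nucleolar protein. The control oligonucleotide had the same length (CCTCCTCCTCCTTCTCCTCCTCCTCC), with cytosine in place of guanine. The study asked how AS1411 alters gene expression in NIH-3T3 mouse fibroblasts. RNA-seq counts were obtained for 3 AS1411 and 3 control libraries at 24 h and for 2 AS1411 and 3 control libraries at 48 h. Total counts per library were 13541951 to 18784497 for AS1411 at 24 h, 14202465 to 17406806 for control at 24 h, 14236610 to 16106724 for AS1411 at 48 h and 14637744 to 18069867 for control at 48 h. The first principal component of log2 CPM held 47.3% of the variance and the second 18.9%. Libraries within each group differed by more than sampling noise, so none was treated as a duplicate. Control replicate 2 at 48 h stood apart from its group, with a chi-square per gene of 9.67 and 13.1 against the other libraries, which differed from each other by 4.77.

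After 24 h with AS1411, transcripts for ribosome production, mitosis and cholesterol synthesis were lower than with the control oligo, and mitochondrially encoded transcripts were higher, by camera with the preset correlation. With an estimated correlation none of these lists was called (smallest adjusted p = 0.0679). Most changes were small. Nucleolin (Ncl, chromosome 1, 86344719 to 86359400, GRCm38), the protein that AS1411 binds, was at 2364 ± 60.1 CPM against 3470 ± 61.6 CPM in control cells (SD, n = 3 each), a log2 fold change of -0.55 ± 0.08 (SE, adjusted p = 4.7e-04). Nucleophosmin (Npm1, chromosome 11, 33152287 to 33163206), another abundant nucleolar protein, changed by -0.59 ± 0.05 (adjusted p = 5.7e-07).

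In all, 1702 genes were higher and 2176 lower among 13040 tested (edgeR quasi-likelihood test, n = 3 and 3), of which 81 and 31 changed at least 2-fold. The 2-fold counts were 37 and 18 with the DESeq2 Wald test, and 39 and 20 at an adjusted p under 0.01. With library-size scaling alone, 2884 were higher and 1201 lower, since that scaling moved the median of all genes to 0.09 on the log2 scale. Using only the 24 h libraries gave 2719 higher genes, and leaving out AS1411 replicate 1 gave 1122. The median absolute log2 fold change of called genes was 0.27.

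The largest rises, as log2 fold change ± SE, were in the microRNA host transcript Mir22hg (1.41 ± 0.17), Snx32 (1.17 ± 0.16), Enpp5 (1.10 ± 0.18), mt-Nd5 (1.09 ± 0.17), mt-Nd4 (1.03 ± 0.18), Ypel3 (0.98 ± 0.15), Inka2 (0.97 ± 0.29), Castor2 (0.97 ± 0.09), Lrrc75b (0.96 ± 0.31) and Fam131a (0.96 ± 0.22). The largest falls were in Prl2c2 (-2.02 ± 0.25), a secreted proliferin with near-identical paralogs, and in Cyp1a1 (-1.57 ± 0.17), a target of the aryl hydrocarbon receptor. They were followed by Fgfbp1 (-1.39 ± 0.33), the chemokine Ppbp (-1.26 ± 0.10), the potassium channel Kcnj2 (-1.23 ± 0.15), Il1rn (-1.18 ± 0.34), Ndnf (-1.12 ± 0.30), Blnk (-1.11 ± 0.15), osteopontin (Spp1, -1.10 ± 0.09) and Gas1 (-1.09 ± 0.13). Adjusted p-values for these genes ran from 1.6e-07 for Ppbp to 0.0351 for Lrrc75b. Without AS1411 replicate 1 at 24 h the calls of Inka2 (0.94), Lrrc75b (0.83), Il1rn (-1.13) and Ndnf (-1.15) were lost, and each was also lost without AS1411 replicate 2 and control replicate 2 at 24 h, among others.

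Of 60 ribosome biogenesis genes, 51 fell and none rose, with a median log2 fold change of -0.26 (53 fell when adjusted over the list alone). Examples besides Npm1 were Rpf2 (-0.37 ± 0.04), Wdr12 (-0.36 ± 0.05) and Taf1d (-0.59 ± 0.08). Camera gave an adjusted p of 7.9e-16, and adjusted p = 0.419 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 59 fell and none rose, with a median of -0.20 (59 when adjusted over the list alone). Among them were Rplp0 (-0.51 ± 0.04), Rpl6 (-0.32 ± 0.04), Rpl14 (-0.31 ± 0.04) and Rps9 (-0.25 ± 0.03). The adjusted p by camera was 7.6e-17, and adjusted p = 0.25 with an estimated correlation. MYC targets outside the nucleolus fell for 16 of 19 members (17 when adjusted over the list alone), at a median of -0.26. They included the mitochondrial chaperonin Hspd1 (-0.37 ± 0.04), Apex1 (-0.40 ± 0.06), Pa2g4 (-0.37 ± 0.05) and spermidine synthase (Srm, -0.27 ± 0.04). The camera adjusted p = 1.2e-07 became adjusted p = 0.381 with an estimated correlation.

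Mitotic genes were lower as well: 44 of 51 G2/M genes fell and none rose, at a median of -0.30 (45 when adjusted over the list alone). The mitotic kinases Plk1 (-0.64 ± 0.04) and Aurka (-0.64 ± 0.05), the kinesin Kif23 (-0.54 ± 0.04) and Cdc20 (-0.56 ± 0.05), an activator of the anaphase-promoting complex, had the smallest adjusted p. By camera the adjusted p was 6.1e-20, and adjusted p = 0.0679 with an estimated correlation. Among G1/S and DNA replication genes 11 of 49 rose and 11 fell (15 and 12 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.754).

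Cholesterol biosynthesis and uptake genes fell for 21 of 24 members (21 when adjusted over the list alone), at a median of -0.62. Examples are squalene synthase (Fdft1, -0.85 ± 0.07), Fdps (-0.75 ± 0.07), squalene epoxidase (Sqle, -0.80 ± 0.07) and Nsdhl (-0.65 ± 0.07). For this list camera gave an adjusted p of 3.2e-13, and adjusted p = 0.25 with an estimated correlation. Fatty acid synthesis genes fell for 9 of 14 members (10 fell and 1 rose when adjusted over the list alone), at a median of -0.18, among them the elongase Elovl6 (-0.67 ± 0.06) and the desaturases Scd2 (-0.82 ± 0.09), Scd1 (-0.32 ± 0.05) and Fads2 (-0.30 ± 0.06). The list test (camera) had an adjusted p of 0.00117, and adjusted p = 0.25 with an estimated correlation. NRF2 targets and heme handling genes fell for 15 of 24 members (17 when adjusted over the list alone), at a median of -0.22, with heme oxygenase (Hmox1, -0.54 ± 0.04), the heme transporter Slc48a1 (-0.51 ± 0.04), G6pdx (-0.32 ± 0.05) and ferritin heavy chain (Fth1, -0.24 ± 0.04). Camera gave an adjusted p of 1.4e-05, and adjusted p = 0.25 with an estimated correlation.

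All 7 mitochondrially encoded mRNAs tested rose, at a median of 0.90 (7 when adjusted over the list alone), with mt-Nd6 (0.95 ± 0.17) and mt-Cytb (0.90 ± 0.16) besides mt-Nd5 and mt-Nd4, and the other 6 listed were not analysed here. The adjusted p by camera was 2.0e-05, and adjusted p = 0.381 with an estimated correlation. Mitochondrially encoded genes took 1.46 ± 0.226% of counts with AS1411 and 0.787 ± 0.097% in control cells (SD, n = 3 each). The 63 tested genes of the nuclear-encoded respiratory chain did not move with them (3 rose and 14 fell, 3 and 13 when adjusted over the list alone, camera adjusted p = 0.243).

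Heat shock genes fell for 14 of 19 members and rose for 1 (14 and 2 when adjusted over the list alone), at a median of -0.24, with Hsp90ab1 (-0.40 ± 0.03), Hspa8 (-0.33 ± 0.04) and Fkbp4 (-0.33 ± 0.04) besides Hspd1. By camera the adjusted p was 8.2e-05, and adjusted p = 0.381 with an estimated correlation. The integrated stress response and amino acid list was called lower (4 of 38 rose and 13 fell, 5 and 14 when adjusted over the list alone, camera adjusted p = 0.0411), with adjusted p = 0.556 with an estimated correlation. Its members with the smallest adjusted p nevertheless went both ways: the stress-induced Nupr1 (0.74 ± 0.08), Atf5 (0.44 ± 0.06) and Ppp1r15a (0.33 ± 0.06) rose, and the serine synthesis enzyme Psat1 (-0.25 ± 0.04) fell. This call was lost with library-size (adjusted p = 0.108) and upper-quartile scaling (0.055), with the CPM filter (0.0576), and without AS1411 replicate 1 (0.102), control replicate 2 (0.0516) or control replicate 3 (0.0603) at 24 h. Of 29 p53 targets 10 rose and 1 fell (11 and 2 when adjusted over the list alone), at a median of 0.15. These were the rises in Dcxr (0.68 ± 0.14), the cell cycle inhibitor Cdkn1a (0.57 ± 0.11) and Polk (0.35 ± 0.07), among others, and the fall in Plk2 (-0.24 ± 0.05). For this list camera gave an adjusted p of 0.0168, and adjusted p = 0.419 with an estimated correlation. TGF-beta targets rose for 5 of 16 members (5 when adjusted over the list alone), among them Ccn2 (0.66 ± 0.08), Pmepa1 (0.18 ± 0.04) and Tagln (0.50 ± 0.12). The camera adjusted p was 0.0244, with adjusted p = 0.419 with an estimated correlation and adjusted p = 0.0668 without AS1411 replicate 1. With the GC and length offsets, an alternative added after seeing the data, the list of TGF-beta targets had a median of 0.06 (adjusted p = 0.0507) and Pmepa1 was at 0.08 (adjusted p = 0.152), so neither passed the threshold.

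The remaining lists were not called at 24 h, and counts adjusted over the list alone stand in brackets where they differ. Rises and falls numbered 4 and 4 (5 and 5) of 20 endoplasmic reticulum chaperones, 9 and 1 of 36 interferon-stimulated genes, 1 and 8 of 26 NF-kB and inflammatory mediators, 3 and 6 of 26 glycolysis and hypoxia genes, 4 and 2 (3 and 2) of 35 extracellular matrix genes, whose median (0.03) and mean (-0.01) differ in sign, and 5 and 3 of 19 SRF targets. They numbered 6 and 2 of 19 YAP/TEAD targets, 12 and 7 (13 and 7) of 37 lysosome and autophagy genes, 5 and 1 of 26 immediate-early genes, 3 and 11 of 29 genes of the mTOR pathway and nucleolin transport, and 2 and 4 of 16 reported nucleolin or G-quadruplex targets. Of 8 adipocyte genes 3 fell. Among marker lists, 1 of 3 neuronal genes fell, and no marker of blood (3 tested), epithelium (1), endothelium (2) or glia (2) passed the test over all genes, though the epithelial one fell when adjusted over the list alone. Of the transport and signalling genes named in advance, Kpnb1 was at -0.15 ± 0.05 (adjusted p = 0.039), a call lost in 15 of 25 alternatives, and Mtor (-0.09 ± 0.06, adjusted p = 0.294) and Kif5b (-0.05 ± 0.04, adjusted p = 0.423) did not pass.

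The number of lists called at 24 h, 12, is weak evidence. None of the 28 tested lists was called with an estimated correlation. Fry, which does not compare a list with the other genes, called 15 lists. Camera with the preset correlation called up to 12 lists in other splits of the same 6 libraries. Those splits hold both treatments on each side in unequal numbers, so they keep part of the real contrast. They do not show how many lists would be called without a treatment effect.

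**Figure D1:**
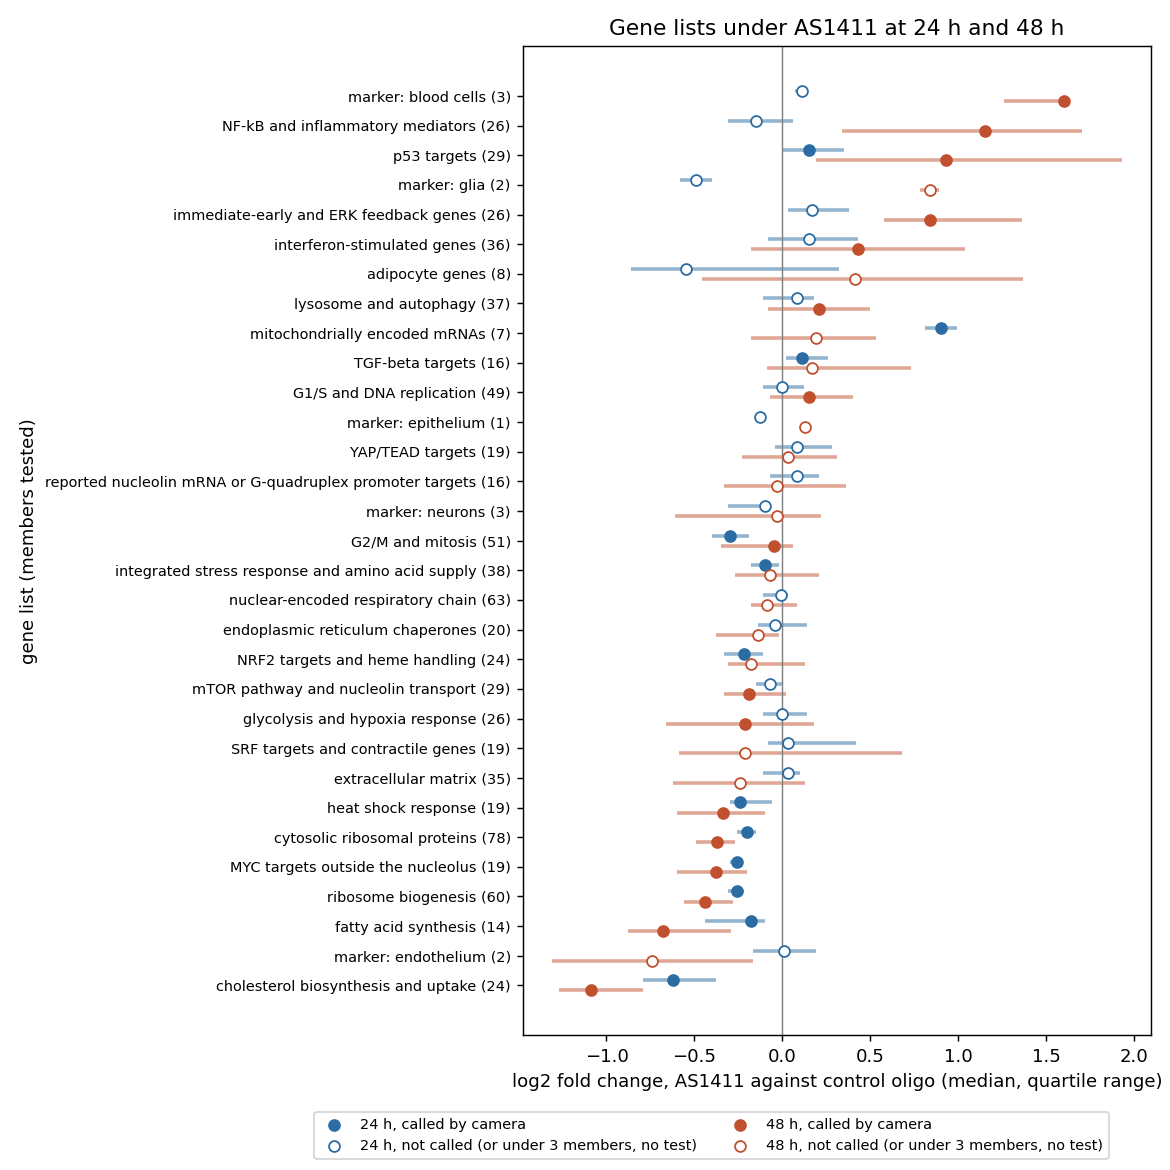
Median log2 fold change (horizontal axis) of each gene list (vertical axis, tested members in brackets) for AS1411 against control oligo at 24 h (blue) and 48 h (red). Lines span the quartiles of the members and filled points were called by camera with the preset correlation; cholesterol genes have the lowest medians called, -0.62 at 24 h and -1.09 at 48 h.

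After 48 h more genes differed, and p53 targets, inflammatory genes and immediate-early genes were higher than in control cells by camera with the preset correlation. With an estimated correlation no list was called (adjusted p = 0.216, 0.24 and 0.24 for these). Of the 26 immediate-early genes, 20 had fallen in control cells since 24 h. The cell cycle inhibitor Cdkn1a (chromosome 17, 29090976 to 29100727) was at 135 ± 25.7 CPM (SD, n = 2) against 14.2 ± 1.82 CPM in control cells (SD, n = 3), and Txnip (chromosome 3, 96557957 to 96561883), which binds thioredoxin, was at 77 ± 4.49 against 7.36 ± 1.33 CPM. Ribosomal and cholesterol synthesis genes were again lower. Ncl was at 1528 ± 176 against 2915 ± 328 CPM (-0.93 ± 0.09, adjusted p = 6.4e-06), and Npm1 changed by -1.0 ± 0.06 (adjusted p = 3.8e-10).

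In all, 3835 genes were higher and 3713 lower (edgeR, n = 2 and 3), of which 907 and 260 changed at least 2-fold. With library-size scaling alone, 5428 were higher and 2372 lower (164 of them at least 2-fold), and the median of all genes moved to 0.16 on the log2 scale. Fold changes given here are relative to TMM scaling. Over both directions, the fit of all libraries called 3878 genes at 24 h and 7548 at 48 h. With only the libraries of each time the counts were 5496 and 6378, a smaller gap between the times.

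The largest rises were Txnip (3.40 ± 0.10), Cdkn1a (3.24 ± 0.11), the phosphatase Ptpn22 (3.12 ± 0.15), the stress-induced factor Atf3 (2.81 ± 0.11), Trp53inp1 (2.74 ± 0.26), the chemokine Ccl2 (2.55 ± 0.10), the eIF2-alpha phosphatase subunit Ppp1r15a (2.54 ± 0.06), Gadd45a (2.41 ± 0.08), Atg9b (2.36 ± 0.22) and Acy3 (2.27 ± 0.15). The largest falls were Gas1 (-2.96 ± 0.16), Kif26b (-2.86 ± 0.54), Prl2c2 (-2.85 ± 0.42), the protease Pappa (-2.78 ± 0.37), the matrix proteins Omd (-2.44 ± 0.38) and Ogn (-2.18 ± 0.36), Il1rn (-2.41 ± 0.42), Fgfbp1 (-2.39 ± 0.37), Ccn5 (-2.29 ± 0.39) and the connexin Gjb2 (-2.18 ± 0.06). Adjusted p-values for these genes ran from 1.6e-15 for Ppp1r15a to 0.00172 for Il1rn. Control replicate 2, which stood apart, had the lowest control level of Omd (15.8 CPM against 31 and 36), Ogn (85.2 against 150 and 168), Il1rn (32.6 against 73.2 and 69.3), Ccn5 (23.8 against 49.1 and 48.7) and Kif26b (4.71 against 7.75 and 14.5). Without it the falls of these genes stayed past the threshold. The AS1411 libraries also differed, with Ogn at 37.9 and 20.8, Il1rn at 14.6 and 7.11, and Ccn5 at 10.5 and 5.8 CPM in replicates 1 and 2. For these genes replicate 2 was thus the lowest library in both treatments at 48 h.

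**Figure D2:**
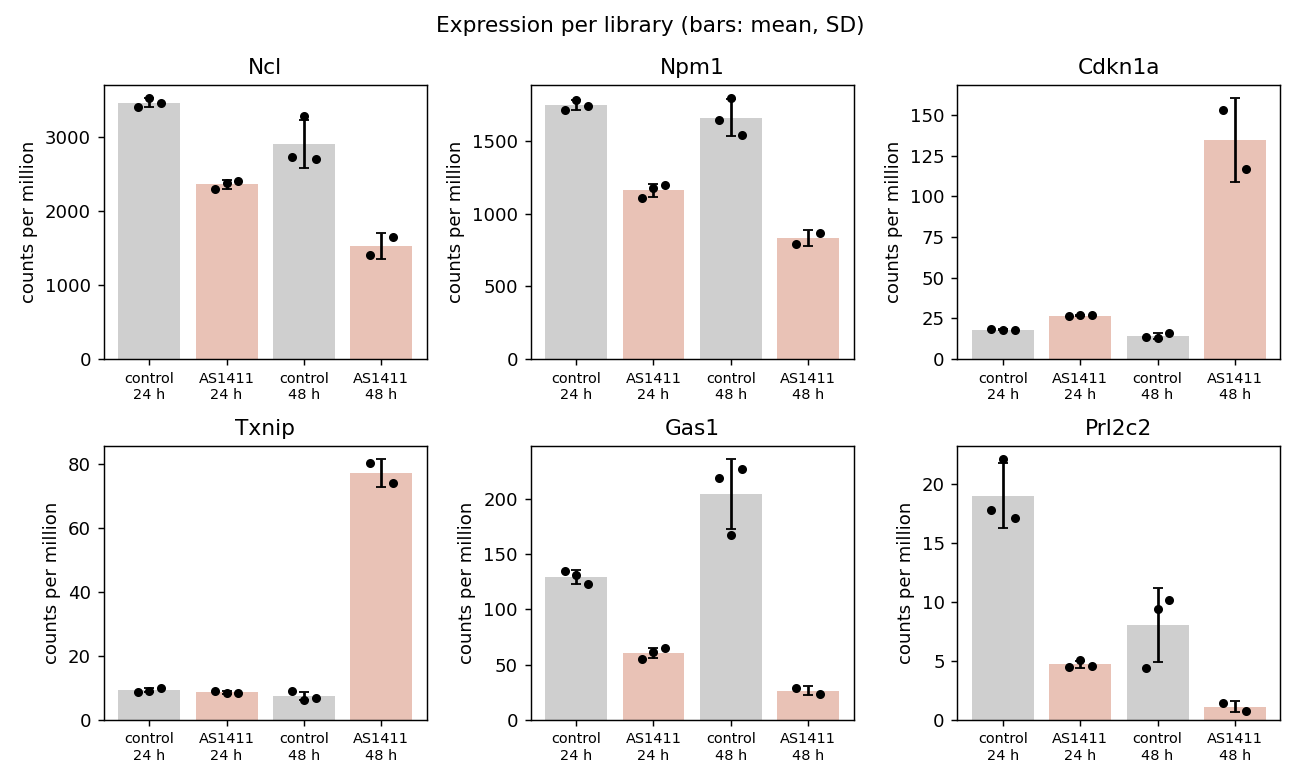
CPM (vertical axes, from 0) of 6 named genes in each library, by treatment and time; bars are means, error bars SD and points single libraries (n = 3, 3, 3 and 2). Ncl, Npm1, Gas1 and Prl2c2 are lower with AS1411 at both times, Cdkn1a reaches 135 CPM and Txnip 77 CPM with AS1411 at 48 h, and Txnip is at 8.56 and 9.26 CPM with AS1411 and control at 24 h.

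Of 29 p53 targets, 21 rose and 2 fell (22 and 2 when adjusted over the list alone), at a median of 0.93. Mdm2 (1.93 ± 0.05), which encodes a ubiquitin ligase for p53, Plk2 (1.23 ± 0.05) and the pro-apoptotic Pmaip1 (2.24 ± 0.12) were higher than in control cells, as was Cdkn1a. The list test (camera) had an adjusted p of 6.1e-07, and adjusted p = 0.216 with an estimated correlation. Plk2 also fell in control cells, from 810 to 829 CPM at 24 h to 357 to 414 CPM at 48 h. With AS1411 it was at 669 to 716 CPM and then at 855 to 907 CPM. NF-kB and inflammatory mediators rose for 18 of 26 members and fell for 5 (18 and 5 when adjusted over the list alone), at a median of 1.15, with the pathway members Nfkb2 (1.22 ± 0.05), Nfkbia (1.28 ± 0.06) and Relb (1.36 ± 0.08) besides Ccl2. Camera gave an adjusted p of 6.5e-04, and adjusted p = 0.24 with an estimated correlation. Immediate-early and ERK feedback genes rose for 21 of 26 members and none fell (21 when adjusted over the list alone), at a median of 0.84, with Maff (1.58 ± 0.07), Ier3 (1.33 ± 0.08) and Zfp36 (1.37 ± 0.10) besides Atf3. The adjusted p by camera was 1.8e-07, and adjusted p = 0.24 with an estimated correlation. Ier3 was lower at 48 h than at 24 h in both treatments. With AS1411 it was at 174 to 191 CPM and then at 153 to 164 CPM. In control cells it was at 134 to 146 CPM and then at 54.1 to 68.0 CPM. Interferon-stimulated genes rose for 21 of 36 and fell for 5 (21 and 5 when adjusted over the list alone), at a median of 0.43, including Cxcl10 (1.37 ± 0.11), Irf9 (0.98 ± 0.10), Eif2ak2 (0.53 ± 0.06) and Tap1 (2.06 ± 0.28). The camera adjusted p was 0.0294, with adjusted p = 0.604 with an estimated correlation, 0.207 with library-size scaling alone, 0.0646 with upper-quartile scaling, 0.0749 without AS1411 replicate 1 and 0.0884 without control replicate 2.

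Ribosome biogenesis genes fell for 50 of 60 members and rose for 1 (52 and 1 when adjusted over the list alone), at a median of -0.44, with the RNA polymerase I factor Ubtf (-0.84 ± 0.05), Rpf2 (-0.59 ± 0.05) and Gar1 (-0.72 ± 0.07) besides Npm1. By camera the adjusted p was 1.3e-11, and adjusted p = 0.419 with an estimated correlation. Cytosolic ribosomal protein genes fell for 67 of 78 members and none rose (68 fell when adjusted over the list alone), at a median of -0.37, with Rplp0 (-0.69 ± 0.04), Rpl14 (-0.66 ± 0.05), Rps15a (-0.56 ± 0.04) and Rps9 (-0.51 ± 0.04). For this list camera gave an adjusted p of 5.1e-15, and adjusted p = 0.216 with an estimated correlation. MYC targets outside the nucleolus fell for 14 of 19 and rose for 1 (14 and 1 when adjusted over the list alone), at a median of -0.38, with Srm (-0.86 ± 0.05), Ldha (-0.74 ± 0.05), Apex1 (-0.80 ± 0.07) and the cap-binding protein Eif4e (-0.58 ± 0.05). The list test (camera) had an adjusted p of 7.8e-05, and adjusted p = 0.419 with an estimated correlation. In the list of the mTOR pathway and nucleolin transport 16 of 29 fell and 5 rose (16 and 6 when adjusted over the list alone), at a median of -0.19, with Rptor (-0.97 ± 0.07), Akt1 (-0.61 ± 0.06), Kpna3 (-0.47 ± 0.05) and Mtor (-0.52 ± 0.07). The camera adjusted p was 0.0231, with adjusted p = 0.334 with an estimated correlation and adjusted p = 0.069 with library-size scaling alone. Kpnb1 changed by -0.42 ± 0.06 (adjusted p = 1.0e-05), and Kif5b did not pass (0.04 ± 0.04, adjusted p = 0.479).

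Cholesterol genes fell for 23 of 24 members (23 fell and 1 rose when adjusted over the list alone), at a median of -1.09, with the regulator Srebf2 (-1.21 ± 0.06), Fdft1 (-1.63 ± 0.08), Fdps (-1.30 ± 0.07) and Nsdhl (-1.26 ± 0.08). Camera gave an adjusted p of 5.0e-11, and adjusted p = 0.24 with an estimated correlation. Fatty acid synthesis genes fell for 12 of 14 and rose for 1 (12 and 1 when adjusted over the list alone), at a median of -0.68, with Elovl6 (-1.74 ± 0.08), Scd1 (-0.89 ± 0.06), Elovl1 (-0.65 ± 0.05) and Acsl3 (-0.70 ± 0.06). The adjusted p by camera was 5.9e-05, and adjusted p = 0.216 with an estimated correlation. Glycolysis and hypoxia genes fell for 13 of 26 and rose for 5 (13 and 5 when adjusted over the list alone), at a median of -0.21, with Pkm (-0.94 ± 0.05), Pfkl (-0.88 ± 0.06) and Aldoa (-0.68 ± 0.04) besides Ldha. The camera adjusted p was 0.0456, with adjusted p = 0.419 with an estimated correlation, and 0.0776, 0.0592 and 0.054 without AS1411 replicate 1, control replicate 1 and control replicate 2. Heat shock genes fell for 14 of 19 and rose for 4 (14 and 4 when adjusted over the list alone), at a median of -0.34, with Hsp90ab1 (-0.79 ± 0.04), Hspa8 (-0.93 ± 0.05), Fkbp4 (-0.86 ± 0.05) and Hspe1 (-0.78 ± 0.05). By camera the adjusted p was 0.00392, and adjusted p = 0.419 with an estimated correlation.

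Cell cycle genes split. Of 49 G1/S and DNA replication genes 24 rose and 10 fell (24 and 10 when adjusted over the list alone), with cyclin E2 (Ccne2, 1.01 ± 0.05), Slbp (0.87 ± 0.04) and Rrm2 (0.80 ± 0.04) higher and the uracil glycosylase Ung (-1.20 ± 0.07) lower (camera adjusted p = 0.0166, adjusted p = 0.419 with an estimated correlation). Of 51 G2/M genes 21 fell and 8 rose (21 and 8 when adjusted over the list alone), at a median of -0.05, with Plk1 (-0.80 ± 0.05), Bub1b (-0.65 ± 0.06), Ect2 (-0.41 ± 0.04) and Cdc20 (-0.49 ± 0.05). The camera adjusted p was 0.0301, with adjusted p = 0.524 with an estimated correlation, and with library-size scaling alone the median was 0.09 and the call was lost (adjusted p = 0.248). It was also lost with upper-quartile scaling (median 0.00, adjusted p = 0.0789) and with the CPM filter (median -0.04, adjusted p = 0.062). Lysosome and autophagy genes rose for 24 of 37 and fell for 8 (25 and 8 when adjusted over the list alone), at a median of 0.21, with Neu1 (0.97 ± 0.07) and Map1lc3b (0.59 ± 0.05) higher and Ctsb (-0.51 ± 0.04) lower. For this list camera gave an adjusted p of 0.0126, and adjusted p = 0.419 with an estimated correlation. All 3 tested blood cell markers, Cd68 (1.66 ± 0.16), Coro1a (1.60 ± 0.21) and Cd14 (0.91 ± 0.14), rose beside the inflammatory and lysosomal lists (3 when adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.216 with an estimated correlation), and the other 10 listed were not tested.

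The lists not called at 48 h, with counts adjusted over the list alone in brackets where they differ, held rises and falls of 13 and 15 (13 and 16) among 38 integrated stress response genes, whose median (-0.07) and mean (0.22) differ in sign, and of 4 and 9 (4 and 10) among 20 endoplasmic reticulum chaperones, 6 and 14 among 24 NRF2 targets, 10 and 24 among 63 nuclear respiratory chain genes, 2 and 0 among 7 mitochondrially encoded mRNAs, and 6 and 15 among 35 extracellular matrix genes. They were 6 and 10 (7 and 10) among 19 SRF targets (median -0.21, mean 0.07), 7 and 6 among 19 YAP/TEAD targets, 6 and 4 among 16 TGF-beta targets, 4 and 6 among 16 reported nucleolin or G-quadruplex targets (median -0.03, mean 0.03), 4 and 2 among 8 adipocyte genes and 1 and 1 among 3 neuronal markers. Of 2 endothelial markers 1 fell, and no epithelial or glial marker passed over all genes, though the 1 epithelial marker rose when adjusted over the list alone. Camera called 16 of 28 lists and none with an estimated correlation, while fry called 23. With 2 AS1411 libraries the spread of that group rests largely on the others.

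The effects at both times overlapped. Of the genes higher at 24 h, 1264 were also higher at 48 h, against 501 for independent lists, and of those lower, 1729 were also lower, against 620 (two-sided Fisher's exact test, p at the floor of 1.0e-300 for each). Across genes, the log2 fold changes had a Pearson r of 0.525 and a Spearman rho of 0.589 (jackknife SE over libraries 0.054 and 0.043). Genes are not independent replicates, and these comparisons share no library. Of 3114 genes called at both times, 121 went in opposite directions, 84 of them lower at 24 h and higher at 48 h.

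The size of the effect differed between the times for 3594 genes, 1749 with a higher and 1845 with a lower log2 fold change at 48 h (edgeR, interaction). Those with the smallest adjusted p were Ppp1r15a (2.20 ± 0.08), Mdm2 (1.71 ± 0.07), Txnip (3.50 ± 0.16), Resf1 (1.79 ± 0.09) and Plk2 (1.47 ± 0.07) in the higher direction. In the lower direction they were Gjb2 (-1.47 ± 0.08), the cadherin Cdh13 (-1.28 ± 0.07), Mgat3 (-1.39 ± 0.09) and Ephb2 (-1.13 ± 0.07). Adjusted p-values of these genes ran from 4.9e-12 to 2.4e-09. With library-size scaling alone 1192 genes were in the lower direction.

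Control cells changed as well between 24 h and 48 h. Ereg, an EGF receptor ligand (-2.14 ± 0.07), Myc (-1.40 ± 0.05), Sgk1 (-1.40 ± 0.05), F3 (-1.48 ± 0.06) and Plk2 (-1.12 ± 0.05) were lower at 48 h, and Lmo7 (0.87 ± 0.04), Mgat3 (0.94 ± 0.05), Idh1 (0.86 ± 0.06), Chd3 (0.74 ± 0.05) and Scd1 (0.72 ± 0.05) were higher. In all, 1513 genes were higher and 1723 lower (edgeR, n = 3 and 3), with adjusted p from 1.6e-13 to 1.8e-08 for the named genes. Of 26 immediate-early genes 20 fell at a median of -0.84 (camera adjusted p = 2.7e-14, adjusted p = 0.141 with an estimated correlation), and 23 of 24 cholesterol genes rose at a median of 0.50 (camera adjusted p = 1.9e-13, adjusted p = 0.205 with an estimated correlation). Lower as well were ribosome biogenesis genes (46 of 60 fell, median -0.25, camera adjusted p = 1.6e-14, adjusted p = 0.502 with an estimated correlation) and NF-kB and inflammatory mediators (14 of 26 fell and 1 rose, median -0.51, camera adjusted p = 8.5e-07, adjusted p = 0.141 with an estimated correlation). Interferon-stimulated genes were higher (15 of 36 rose, median 0.45, camera adjusted p = 3.5e-05, adjusted p = 0.45 with an estimated correlation). So were genes of fatty acid synthesis (7 of 14 rose, median 0.36, camera adjusted p = 1.6e-05, adjusted p = 0.141 with an estimated correlation), glycolysis and hypoxia (9 of 26 rose and 1 fell, median 0.13, camera adjusted p = 1.1e-04, adjusted p = 0.205 with an estimated correlation) and endoplasmic reticulum chaperones (12 of 20 rose, median 0.15, camera adjusted p = 2.5e-05, adjusted p = 0.517 with an estimated correlation). Called lower with smaller medians were cytosolic ribosomal protein genes (-0.05), YAP/TEAD targets (-0.14), TGF-beta targets (-0.16) and MYC targets outside the nucleolus (-0.14). Camera gave adjusted p = 0.00893, 0.00389, 0.0336 and 0.0065 for these, and adjusted p = 0.569, 0.45, 0.517 and 0.569 with an estimated correlation. When adjusted over the list alone, 22 immediate-early, 49 ribosome biogenesis and 14 NF-kB genes fell and 23 cholesterol, 16 interferon-stimulated, 8 fatty acid, 12 glycolysis and 13 chaperone genes rose. In AS1411 cells the immediate-early and cholesterol lists had medians of -0.09 and 0.02 over that interval and were not called. Members went both ways: 5 of 26 immediate-early genes rose and 10 fell, and 6 of 24 cholesterol genes rose and 7 fell. The fatty acid and glycolysis lists were not called there either, at medians of -0.02 (3 of 14 rose and 3 fell) and -0.14 (6 of 26 rose and 10 fell). The count of lower genes was 1146, 1125 and 1147 without control replicate 1, 2 or 3 at 24 h.

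**Figure D3:**
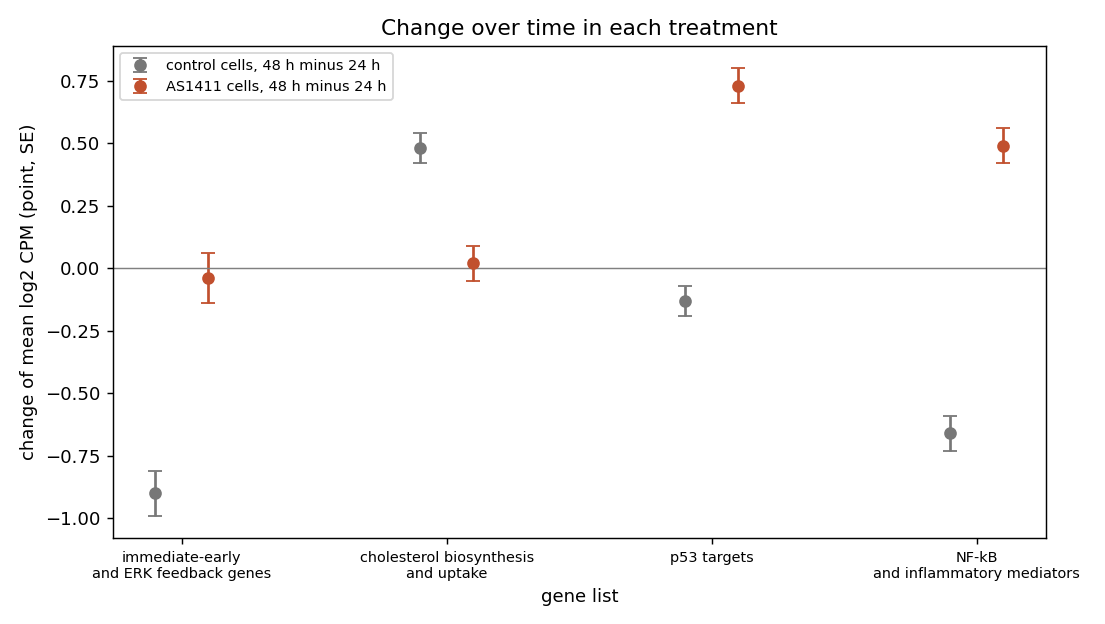
Change of the mean log2 CPM of 4 gene lists between 24 h and 48 h (vertical axis) in control cells (grey) and AS1411 cells (red); points are differences of group means and bars SE from the spread pooled over the groups. Immediate-early genes change by -0.90 in control cells and -0.04 in AS1411 cells, and p53 targets by -0.13 and 0.73.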

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

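The tests of scaling, of shared sequence, of GC content and length, of the time change in control cells and of selenium supply were chosen after the results had been seen.

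The effect of AS1411 differed between 24 h and 48 h, by the interaction term of the edgeR model, for 1749 genes in the higher and 1845 in the lower direction. It also differed for 14 lists by camera with the preset correlation and for 96 of the 132 named genes. Most named genes were chosen by their effects in the same data, so that share is no further evidence. Of all tested genes 27.6% differed. Values in brackets are log2 differences, the 48 h effect minus the 24 h effect. Such a difference can come from the change over time in AS1411 cells, in control cells or in both. The list medians were ribosome biogenesis (-0.17), cytosolic ribosomal proteins (-0.17), p53 targets (0.65), G1/S and DNA replication (0.08), G2/M and mitosis (0.16), NF-kB and inflammatory mediators (1.07), cholesterol biosynthesis and uptake (-0.48), fatty acid synthesis (-0.44), glycolysis and hypoxia response (-0.31), mitochondrially encoded mRNAs (-0.68), SRF targets and contractile genes (-0.17), lysosome and autophagy (0.10), immediate-early and ERK feedback genes (0.83) and blood cell markers (1.43). With an estimated correlation none of these lists was called (smallest adjusted p = 0.127). Named genes with a higher effect at 48 h were Txnip (3.50), Ptpn22 (2.95), Cdkn1a (2.68), Ccl2 (2.55), Atf3 (2.53), Ppp1r15a (2.20), Gadd45a (2.04), Trp53inp1 (2.04), Cyp1a1 (2.01), Resf1 (1.79), Acy3 (1.78) and Pmaip1 (1.75). Further genes in this direction were Mdm2 (1.71), Cxcl10 (1.69), Cd68 (1.56), Nfkbia (1.47), Plk2 (1.47), Atg9b (1.47), Coro1a (1.43), Relb (1.41), Ereg (1.38), Nfkb2 (1.32), Maff (1.17) and Ccn2 (1.04). In the same direction went Zfp36 (1.02), Ier3 (0.96), Cd14 (0.88), Blnk (0.84), Dcxr (0.83), Rrm2 (0.83), Slbp (0.82), Ccne2 (0.73), Polk (0.65), Nupr1 (0.65), Hmox1 (0.61) and Kif23 (0.58). The remaining positive differences were those of Irf9 (0.56), Neu1 (0.54), F3 (0.51), Spp1 (0.44), Myc (0.30), Map1lc3b (0.26), Eif2ak2 (0.25) and Aurka (0.21). Named genes with a lower effect at 48 h began with Rplp0 (-0.17), Sgk1 (-0.20), Kpna3 (-0.22), Rpf2 (-0.22), Pa2g4 (-0.25), Rps9 (-0.26), Kpnb1 (-0.27), Atf5 (-0.28), Eif4e (-0.32), Rps15a (-0.35), Akt1 (-0.36) and Rpl14 (-0.36). Also in the lower direction were Ncl (-0.38), Slc48a1 (-0.38), Hsp90ab1 (-0.39), Apex1 (-0.40), Npm1 (-0.41), Mtor (-0.42), Gar1 (-0.45), Hspe1 (-0.46), Elovl1 (-0.48), Psat1 (-0.50), Ldha (-0.50) and Idh1 (-0.50). To these belong Fkbp4 (-0.54), Acsl3 (-0.54), Fdps (-0.55), Aldoa (-0.56), Fads2 (-0.56), Pkm (-0.57), Scd1 (-0.57), Ubtf (-0.57), Srm (-0.59), Hspa8 (-0.60), Nsdhl (-0.61) and Lmo7 (-0.64). Other such genes were Scd2 (-0.72), Fdft1 (-0.78), Srebf2 (-0.81), Pfkl (-0.85), Ung (-0.89), Rptor (-0.93), Sqle (-0.93), mt-Cytb (-0.97), Elovl6 (-1.07), Ephb2 (-1.13) and Cdh13 (-1.28). The last were Mgat3 (-1.39), Gjb2 (-1.47), Ogn (-1.82), Gas1 (-1.87) and Pappa (-2.49). The named genes were not sorted by which cells changed, and examples differ (mean CPM at 24 h and 48 h). Txnip went from 8.56 to 77 with AS1411 and from 9.26 to 7.36 in control cells. Ccn2 fell in both, from 1636 to 832 with AS1411 and from 1037 to 256 in control cells. Scd2 rose in both, from 461 to 825 with AS1411 and from 813 to 2406 in control cells.

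Ribosomal protein and ribosome biogenesis lists were called lower at both times by camera with the preset correlation, but not with an estimated one (adjusted p = 0.25 and 0.419 at 24 h, and 0.216 and 0.419 at 48 h). Leaving out the TMM factors shifts all genes together (median of all genes at 48 h from 0.01 to 0.16). With library-size scaling alone the list medians at 48 h moved from -0.37 and -0.44 to -0.22 and -0.29. The upper quartiles (-0.12 and -0.13) stayed below 0. The lists were thus lower under either scaling, which argues against the TMM factors as the whole cause and says no more than that. Comparisons with the median of all genes were set aside, as a shared factor cannot change them. The absolute change stays open without spike-ins. A trend with GC content and length is argued against as well, since with both removed the medians stayed at -0.35 and -0.44. Reads shared with pseudogenes stay open for the ribosomal protein genes: 7 of 78 had at least 90% of their 51-base stretches in no annotated transcript of another gene, and their median was -0.33 against -0.37 in the other 71, but 7 genes are under the 10 set for the test, and an earlier version (18 genes with no pseudogene named after them, -0.37) was set aside because it misses pseudogenes with numbered names. A change in growth or nucleolar function under AS1411 may also underlie the pattern and was not tested apart from these.

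At 48 h immediate-early genes were higher and cholesterol genes lower with AS1411 than in control cells, while both lists changed over time in control cells. For immediate-early genes, the mean log2 CPM changed by -0.04 ± 0.10 (SE) in AS1411 cells and by -0.90 ± 0.09 in control cells. The contrast of this mean was 0.15 ± 0.09 at 24 h and 1.01 ± 0.10 at 48 h. Its growth thus came from the fall in control cells, as the mean in AS1411 cells changed by less than its SE. This holds for the list mean and not for each member: in AS1411 cells 5 of the 26 members rose and 10 fell. Among those that rose were Atf3 at 2.07 and Zfp36 at 0.93, against -0.46 and -0.09 in control cells. Why the mean did not fall with AS1411 stays open. For cholesterol genes the control cells' change (0.48 ± 0.06) cannot be the whole cause, since the contrast was already -0.55 ± 0.06 at 24 h. The contrast was -1.01 ± 0.07 at 48 h, while the mean in AS1411 cells changed by 0.02 ± 0.07 between the times. For the list mean, the growth of this contrast thus came from the rise in control cells. In AS1411 cells 6 of the 24 members rose and 7 fell. The control library that stood apart at 48 h is argued against for both lists, because without it the contrasts were 1.09 ± 0.10 and -0.98 ± 0.07, at least 11.3 SE from 0. What made control cells change (density, medium or the oligo itself) was not tested, since no untreated cells were analysed here.

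The median of selenoprotein transcripts was lower with AS1411 in a list added after seeing the data: 9 of 18 fell and 1 rose at 24 h, and 11 fell and 5 rose at 48 h (camera adjusted p = 2.1e-04 and 0.0295, and adjusted p = 0.231 and 0.357 with an estimated correlation). A GC and length trend as the whole cause is argued against, since with it removed the median at 48 h was -0.44 against -0.45 before, members shifted by -0.08 to 0.12, and the list stayed called (camera adjusted p = 0.0338, adjusted p = 0.295 with an estimated correlation); an earlier bound on the upper quartile was set aside because the quartile was 0.09 before the correction too. Lower selenium supply, which would lower Gpx1, Selenow, Selenoh and Msrb1 most, may account for part: these 4 had a mean of -0.64 against -0.16 for the others at 24 h (exact permutation over 3060 sets, one-sided p = 0.0098), but -0.48 against -0.15 at 48 h (p = 0.205). Msrb1 was at 0.11 ± 0.06 and 0.20 ± 0.07, against that hypothesis. Because the 4 genes were chosen after Gpx1 had been seen to fall, and a low p at both times was asked for only after the p at 24 h, which alone would have counted for the hypothesis, had been seen, these p-values do not decide it.

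Splits of the 6 libraries at 24 h are too few for a share under 0.05, with 10 in all. The real split gave 3878 genes and the highest of the others 0, so 1 of 10 gave as many. For time in control cells the real split gave 3236 genes and the highest other 0, again 1 of 10. For lists at 24 h, 2 of 10 splits gave at least the real 12, the highest other being 12. In every other split, each side held both groups in unequal numbers, so part of the real difference stayed between the sides. The rest of that difference added to the spread within the sides. The counts of the other splits are therefore no measure of what arises without a group effect. They decide nothing for genes or for lists.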

How the results depend on the processing

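The offset for GC content and length was added after seeing the data. Of 168 values of named genes, 160 kept their direction and side of the threshold in every alternative run, and none reversed. The exceptions were Kpnb1, Lrrc75b, Il1rn, Ndnf, Inka2, Pmepa1 and Tagln at 24 h, which lost their call in 15, 11, 8, 7, 6, 1 and 1 of 25 alternatives, and Kif5b at 48 h, which passed with library-size scaling alone. Most named genes were chosen for a large effect or a small adjusted p in the same data. Calls in general were less stable. Of all 3878 genes called at 24 h, 68.2% to 76.5% kept their call without 1 of the 24 h libraries. With library-size scaling alone 74.9% kept it, and at 48 h 82.2% of 7548. For time in control cells, 59.7% of 3236 kept it with the replicate block within time. Of 56 list results 13 kept their side in all alternatives. The integrated stress response list at 48 h pointed lower without a call by camera but was called higher by fry (adjusted p = 0.0145), which tests another hypothesis. Its members' median (-0.07) is the same in both, and their mean is 0.22, so the values did not change, only the direction the test reads from them. With an estimated correlation 0 lists were called in either direction at 24 h and at 48 h, against 3 higher and 9 lower, and 7 higher and 9 lower; with fry 11 were higher at 48 h. With library-size scaling alone the counts were 2884 higher and 1201 lower at 24 h, 2372 lower at 48 h and 1192 lower for the interaction, because this scaling shifts all genes. Fitting only the 24 h libraries gave 2719 higher genes. Libraries of a group differed by a chi-square per gene of 1.54 to 3.13 at 24 h and of 4.01 to 13.1 at 48 h. Without control replicate 2 at 48 h, which is in neither 24 h group, the 24 h calls rose from 3878 to 4769. With only the 24 h libraries 5496 genes were called, and 99.3% of the 3878 kept their call. The spread of the 48 h libraries thus bears on the 24 h calls. That fit also redid the filter and the scaling and had fewer libraries, so the share of the spread alone was not tested. With only the groups compared, 6378 genes were called at 48 h (84% of 7548 kept). For time in control cells 2400 were called (73.7% of 3236 kept). An adjusted p under 0.01 gave 898 higher and 1403 lower at 24 h, 966 and 1040 for the interaction, and 830 and 1033 for time in control cells, by construction. The correlation of the effects at both times was 0.357 (rho 0.499) with no count filter and 0.603 with the CPM filter, as more or fewer low-count genes entered.

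At 24 h the replicate numbers did not pair the samples: deviations of same-numbered AS1411 and control libraries correlated at -0.03, 0 and -0.05. At 48 h, with only 2 pairs, same-numbered libraries correlated at 0.12 and 0.21, and the others at -0.21, 0.12, -0.12 and -0.12. With 2 AS1411 libraries the deviations of that group mirror each other, so these values are not independent. A factor shared by the replicate 2 libraries at 48 h stays open. With the replicate block, 1738 genes were higher and 2225 lower at 24 h, and 3780 and 3659 at 48 h, and the glycolysis list at 48 h lost its call (adjusted p = 0.0609) while the interferon list at 24 h gained one (adjusted p = 0.0303). With the replicate block within time, 961 were higher for time in control cells and 5 lists were higher at 24 h (interferon and immediate-early genes gained a call, adjusted p = 0.0136 and 0.00915), the G2/M and glycolysis lists lost theirs at 48 h (adjusted p = 0.0618 for each), and the cause was not tested.

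Leaving out each library in turn gave 1122 to 2225 higher and 1524 to 2544 lower genes at 24 h, lowest without AS1411 replicate 1 and without control replicate 2 at 24 h in turn. The ranges were 3067 to 3901 and 3182 to 3796 at 48 h, 1218 to 2039 and 1427 to 2238 for the interaction, and 1092 to 1931 and 1125 to 2030 for time in control cells, where leaving out control replicate 1, 2 or 3 at 24 h gave 1146, 1125 and 1147 lower genes. Lists numbered 2 to 5 higher (5 without AS1411 replicate 3 at 24 h or control replicate 3 at 48 h) and 8 to 10 lower at 24 h, and 6 to 7 higher and 8 to 10 lower at 48 h. Pearson r ran from 0.468 to 0.527 and rho from 0.542 to 0.594, lowest without AS1411 replicate 1 at 48 h. Without a 48 h AS1411 library 1 is left in that group, and it is assumed to vary like the other groups. In the simulations, which changed few of the genes, small changes were missed: of the smallest fold simulated, 57.6% of genes were recovered at 24 h and 50.2% at 48 h.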

Other observations

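Host transcripts of small nucleolar RNAs, a list added after seeing the data, did not move as a group. Of 11 tested, 1 rose and 2 fell at 24 h (camera adjusted p = 0.49) and 3 rose and 1 fell at 48 h (adjusted p = 0.32). Gas5 was at -0.48 ± 0.09 and -0.38 ± 0.10, Snhg5 at -0.57 ± 0.07 and -0.19 ± 0.08, and Snhg12 at 0.00 ± 0.09 and 1.18 ± 0.09 at 24 h and 48 h (log2 fold change ± SE, genes picked after their values were seen). Mitochondrially encoded genes took 1.13 ± 0.0835% of counts with AS1411 at 48 h (SD, n = 2) and 1.02 ± 0.185% in control cells (n = 3), a smaller gap than at 24 h.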
